A study of Mus musculus with 48 samples.

How the data were processed

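PolyA-selected, stranded mRNA libraries from liver and from visceral white adipose tissue were sequenced from male and female mice that started a high-fat diet (HFD, 45% of calories from fat) or a regular diet (RD) at 8 weeks of age and were taken after 2 or 12 weeks. Per the labels 200 ng of RNA went into each library. Tissue, sex, diet and weeks on the diet give 16 groups of 3 libraries, and the groups were taken from the sample names and labels. No library was left out.

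The deposited gene table holds expected counts per gene symbol, estimated by the authors before deposit. Their processing notes name kallisto, edgeR, DESeq2 and GRCm38 without roles or versions, so how the counts were summed per gene is not given in the sources used here. It has 30055 gene symbols in 48 libraries, 36.6% of its values are 0, and 0.094% of the values above 0 are whole numbers within a tolerance of 1e-06. Library totals, as sums of expected counts, ran from 44.7 to 105.4 M. Reads, alignments and transcript-level values were not analysed here, so reads shared between near-identical genes could not be reassigned. Positions were taken from GENCODE M21 on GRCm38, in which 93.8% of the symbols have exactly 1 position.

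Expected counts were rounded, and each tissue was fitted alone with its 24 libraries in 8 groups. The tools were edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, with tables handled in Python 3.11.15. Genes passed filterByExpr by group, TMM scaled the libraries, and glmQLFit ran with robust = TRUE. Each tissue had 10 contrasts: sex on each diet, diet in each sex and the sex by diet interaction, at each time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. In the interaction a positive value means a higher HFD over RD ratio in females. Log2 CPM values used a prior count of 2. The SE of a fold change was taken as its absolute log2 value over the square root of the quasi-likelihood F, an approximation. Where a group had 0 counts a fold is given as a lower bound against a floor of 3 counts per library.

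Gene lists, contrasts, alternatives and the rule for naming genes were fixed before the data were examined. Of 822 symbols on 47 lists, 809 were found, 6 of them under an older symbol. Lists were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. List p values were adjusted over all lists and contrasts of a tissue, 320 tests in liver and 360 in adipose tissue. Members past the threshold were counted over all genes and with p adjusted over the list alone. For diet contrasts at 12 weeks and sex contrasts on RD the rule names the 6 genes with the highest and the 6 with the lowest fold change, and elsewhere 3 and 3. These need a call, a mean log2 CPM of at least 1 and a symbol that is not a predicted-gene name. Outside the interactions they also need no overlap between the replicates compared. Genes of the sex chromosome list and Y-linked genes were left out. Up to 4 members of each list were added by smallest p. Some genes that the rule selects are not reported here.

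The sex index of a library is the mean log2 CPM of female-biased genes minus that of male-biased genes. Its genes were called on RD in the other cohort at an absolute log2 fold change of at least 1, so no library was scored with genes chosen from it. The interaction of the index was tested by shuffling the diet labels within each sex over all 400 arrangements, as an exact two-sided permutation test. The test is exact where diet has no effect in either sex. It is not exact where diet has an equal effect in both. Overlaps between contrasts are given beside the number expected from independent calls.

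The count test was tested on simulated data with the dispersions of each tissue, in which 200 genes were changed. Of the called genes 3.2% in liver and 2.2% in adipose tissue were false. Changes of 1.5, 2, 4 and 8-fold were recovered for 20, 50, 85.7 and 90% of genes in liver and 4, 34, 66 and 80% in adipose tissue. Random lists gave a camera p under 0.05 in 0.5% and 2.5% of draws. The simulated counts were drawn independently for each gene, without variation shared between genes. These rates of false calls and list calls therefore need not hold for the real libraries. Sex labels were checked by Y-linked genes, and replicates were checked for duplicate libraries, of which none were found. Male adipose libraries at 12 weeks with the same animal number correlated best with each other (r = 0.108, 0.134 and 0.154 over centred values across genes), so the number was used there as a block in an alternative. In liver and in females at 2 weeks shared numbers did not all match best. The labels do not say what a shared number stands for.

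The alternatives were DESeq2, median-of-ratios size factors, no filter beyond a total count above 0, a fit of the compared groups alone, robust = FALSE, the replicate number as a block where groups share numbers, and each library left out in turn. For the sex index, gene choice, medians, prior count and each library were varied. After the data were seen, a fit of the adipose libraries with the scores of the epididymis and mammary epithelium lists as covariates was added, and the adipose interaction at 12 weeks was fitted with the animal number of the males as a block. The sex index there was also tested with diet exchanged only within pairs of males that share a number. Every contrast was also recomputed over other splits of the same libraries, all 10 for 3 against 3 and 40 drawn for the interaction. For adipose tissue at 12 weeks the splits were also compared by how many pairs of male animal numbers they part and by whether they keep the diet groups of one sex whole.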

Results

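Messenger RNA from the liver and the visceral white adipose tissue of male and female mice was sequenced after 2 or 12 weeks on a high-fat diet (HFD) or a regular diet (RD). The 48 libraries fall into 16 groups of 3 animals, set by tissue, sex, diet and weeks on the diet, and none was left out. Total expected counts ran from 50.9 to 80.1 M per liver library, with a median of 69.9 M. They ran from 44.7 to 105.4 M per adipose library, with a median of 63.2 M. Levels below are CPM (counts scaled to library size), mean ± SD with n = 3 per group. Changes are log2 fold changes, female over male or HFD over RD, ± an approximate SE derived from the edgeR F statistic. Intervals after ± for fold changes and the floors on fold changes cover the fit or counting error alone. The words rose, fell, higher and lower are used of genes with a Benjamini-Hochberg adjusted p under 0.05, and positions refer to GRCm38. For list members, counts with 1 library left out run from the lowest to the highest over the libraries compared, and counts in the groups alone come from a fit of those libraries only.

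Y-linked transcripts were checked against the sex labels of the libraries. Ddx3y, a Y-linked RNA helicase, had at most 0.877 CPM in the 24 female libraries and at least 40.6 CPM in the 24 male libraries. Eif2s3y had at most 0.268 and at least 32.2 CPM. Transcripts of reproductive tract epithelium were present in part of the male adipose libraries. Crisp1, a secreted protein of the epididymis (chromosome 17, 40293758 to 40319207), had 3050, 3020 and 5450 CPM in the 3 RD males at 12 weeks and 6.3, 1.89 and 1.14 CPM in the 3 HFD males. At 2 weeks its level was 970, 0.586 and 2680 CPM in RD males 6, 7 and 8 and 3.05, 6500 and 6.29 CPM in HFD males 12, 13 and 14. RD male 6 at 2 weeks stood apart with 2980 CPM of Gpx5 and 1540 CPM of Lcn8, further epididymal transcripts, and the 3 RD males at 12 weeks had at most 1.02 CPM of Gpx5. None of the 15 measured epididymis markers reached a median of 1 CPM in the female libraries, in which Crisp1 stayed at or below 0.0559 CPM. Among females, HFD animal 1 at 2 weeks had 298 CPM of the epithelial cadherin Cdh1 and an adipocyte score (mean log2 CPM of the list) of 8.34, beside 10.12 and 9.98 in the other HFD females.

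Females and males on RD were compared to find the liver transcripts that differ by sex without high-fat feeding. At 2 weeks the P450 gene Cyp2b13 (chromosome 7, 26061497 to 26096197) had 133 ± 15.7 CPM in females and 0.014 ± 0.0141 CPM in males (n = 3 each). Cyp2b9 (476 ± 41.9 against 0.0738 ± 0.0568 CPM) and Cyp3a41a (2970 ± 346 against 0.345 ± 0.332 CPM) were higher in females too, as was A1bg by 12.8 ± 1.14. Cyp4a12a, a fatty acid hydroxylase (chromosome 4, 115299046 to 115332815), had 461 ± 57.1 CPM in males and 0.634 ± 0.963 CPM in females. Hsd3b5, a steroid dehydrogenase, had 319 ± 99.2 and 3.8 ± 2.85 CPM. The major urinary protein genes Mup7 and Mup20, which encode pheromone carriers, had log2 fold changes of -8.67 ± 0.56 and -7.76 ± 0.38. The ferritin receptor Scara5 had -7.54 ± 0.44. The 12-week cohort gave 11.75 ± 0.53 for the sulfotransferase Sult2a1, -10.48 ± 0.91 for Hsd3b5 and -7.67 ± 0.65 for the transporter Slc22a28. Near-identical Cyp2, Cyp3, Cyp4 and Mup genes can share reads, so the levels of single members are uncertain.

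Of the 32 female-biased liver genes fixed beforehand, 29 were higher and 1 lower in females at 2 weeks (31 and 1 adjusted over the list alone). At 12 weeks 31 were higher and 1 lower (31 and 1 adjusted over the list alone). The member that went the other way was Srd5a1, a steroid reductase, at -1.27 and -2.02. Among the 38 male-biased genes 33 were lower in females at 2 weeks and 32 at 12 weeks (34 and 35 adjusted over the list alone). Ihh, a signalling ligand, was the exception, higher at 2 weeks by 1.30. The limma camera test gave adjusted p = 4e-58 and 4.9e-54 for the female-biased list and 1.6e-50 and 1.6e-62 for the male-biased list. These list calls hold with an estimated correlation, as do those of both lists on HFD. The diet calls that hold are cholesterol synthesis in females and the NRF2 genes in both sexes, all in liver at 2 weeks. In adipose tissue the lipid-associated macrophage call between the sexes on HFD at 12 weeks holds, and no other list call does.

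Immune genes also differed between the sexes in liver on RD. B cell markers were higher in females for 7 of 15 members at 2 weeks and 8 at 12 weeks (9 and 9 adjusted over the list alone). The 2-week count was 4, 3, 3 and 4 without female 1 or 4 or male 7 or 8, and 4 with no filter. The 12-week count was 4, 4 and 3 without female 8 or male 2 or 4, and 5 in the groups alone. At 2 weeks Igj, the immunoglobulin J chain, had 13.8 ± 4.12 against 1.12 ± 0.388 CPM and Igkc 51.6 ± 15.9 against 5.07 ± 3.36 CPM. Their camera adjusted p was 2.2e-06 and 1.2e-05, with medians of 0.95 and 1.26 (adjusted p = 0.16 and 0.19 with an estimated correlation). At 12 weeks 13 of 20 interferon response genes were higher in females (17 adjusted over the list alone, median 1.11, camera adjusted p = 3.8e-11, adjusted p = 0.19 with an estimated correlation). Ifi44 was higher by 1.96 ± 0.27 and Oasl2 by 1.38 ± 0.23. Macrophage markers were higher for 11 of 18 members (15 adjusted over the list alone, median 0.81, camera adjusted p = 5.1e-06, adjusted p = 0.48 with an estimated correlation). This count was not stable. It was 0 without female 8 or male 4, and 3, 4 and 7 without male 2, male 3 or female 5. It was 3 in the groups alone and 5 with no filter. The macrophage scores of RD males 2, 3 and 4 were 3.73, 3.77 and 3.59. Csf1r had 95.9 ± 34.1 against 51.2 ± 6.26 CPM. In RD female 8 the interferon score was 4.56 and the macrophage score 4.98, beside 3.62 and 3.87 and beside 4.21 and 3.87 in the other RD females. The edgeR quasi-likelihood test called 1560 of 15897 genes at 2 weeks (853 higher and 707 lower in females) and 1400 at 12 weeks (895 and 505). Of these, 359 were higher and 297 lower in both cohorts where 48 and 22.5 are expected from independent calls. The 2-week count was 831, 990, 835, 929 and 779 without female 1, 2 or 4 or male 7 or 8, and 2965 in a fit of these 6 libraries alone. More genes were lower than higher in females in that fit (1329 higher and 1636 lower), with no filter (574 and 790) and without male 7 (422 and 507). Without female 8, male 2 or male 4 the 12-week count was 706, 807 and 755.

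On HFD, the comparison of females with males asks which liver transcripts differ by sex under high-fat feeding. At 2 weeks Cyp4a14, a fatty acid omega-hydroxylase, had 1300 ± 900 CPM in females and 17 ± 7.43 CPM in males (n = 3 each). Vnn1, a pantetheinase, had 130 ± 57.6 and 37.5 ± 10.6 CPM. Acute phase genes were lower in females, with the haemoglobin-binding protein Hp at 2350 ± 778 against 8160 ± 4990 CPM and the transport protein Orm1 at 533 ± 234 against 2040 ± 1640 CPM. Cholesterol synthesis genes were lower in females as well, with Idi1, an isoprenoid isomerase (chromosome 13, 8885501 to 8892451), at 93.5 ± 13.4 against 276 ± 26.2 CPM and Msmo1 at 65.1 ± 8.38 against 209 ± 44.8 CPM. Cyp3a41b was at least 975-fold higher in females, against a floor of 3 counts per library. By list, 12 of 28 fatty acid oxidation genes were higher in females (13 higher and 1 lower adjusted over the list alone, 4 higher in the groups alone, camera adjusted p = 1.6e-05, adjusted p = 0.595 with an estimated correlation). The acute phase list had 14 of 20 members lower (14 adjusted over the list alone, 6 to 14 with 1 library left out, 4 in the groups alone, camera adjusted p = 3.6e-07, adjusted p = 0.48 with an estimated correlation). The cholesterol list had 12 of 25 lower (16 adjusted over the list alone, 7 in the groups alone, camera adjusted p = 1.1e-10, adjusted p = 0.31 with an estimated correlation). The acute phase score was 10.28 in HFD male 13 and 7.42 and 8.23 in HFD males 12 and 14. The albumin transcript Alb was at 97600 ± 5310 CPM in females and 43800 ± 5520 CPM in males.

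At 12 weeks on HFD, markers of macrophages and of Kupffer, stellate and endothelial cells included genes higher in females, and those of bile duct cells did not. Csf1r, the macrophage growth factor receptor (chromosome 18, 61100598 to 61132149), had 91.1 ± 10.4 CPM in females and 17.8 ± 5.49 CPM in males (n = 3 each). Emr1, the F4/80 antigen, had 35 ± 8.61 and 5.39 ± 1.46 CPM. Of 18 macrophage markers 16 were higher (17 adjusted over the list alone, median 1.40, camera adjusted p = 9.8e-14, adjusted p = 0.19 with an estimated correlation). Kupffer cell markers were higher for 8 of 13 members (10 adjusted over the list alone), led by Vsig4 at 1.95 ± 0.23 and Cd5l at 2.21 ± 0.35 (adjusted p = 0.37 with an estimated correlation). C6, a complement component on that list, was lower, at -4.5 ± 0.3. Stellate cell markers were higher for 10 of 14 members (12 adjusted over the list alone, 6 to 11 with 1 library left out, 3 in the groups alone, adjusted p = 0.15 with an estimated correlation), with Hgf at 7.77 ± 1.34 against 1.69 ± 0.775 CPM. Endothelial markers were higher for 9 of 12 members (9 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), with Cdh5 at 37.7 ± 3.9 against 15.8 ± 2.51 CPM. Of 9 bile duct markers 0 were higher and 1 lower (0 adjusted over the list alone, 0 to 1 lower with 1 library left out, median -0.23, adjusted p = 0.972 with an estimated correlation). The bile duct scores were 0.57, 0.49 and 0.26 in HFD females 3, 6 and 7 and 0.17, 0.78 and 0.85 in HFD males 2, 3 and 4. Unfolded protein response genes were lower in females for 10 of 19 members (14 adjusted over the list alone, 1 to 14 with 1 library left out, 1 in the groups alone, adjusted p = 0.48 with an estimated correlation), with the chaperone Hspa5 at 652 ± 234 against 1840 ± 1640 CPM. The unfolded protein score was 7.11 in HFD male 4 and 5.75 and 6.12 in HFD males 2 and 3. Of the 38 male-biased genes 33 were lower in females (36 adjusted over the list alone), and of the 32 female-biased genes 30 were higher and 1 lower (30 and 1 adjusted over the list alone).

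Between the sexes on HFD edgeR called 1971 genes at 2 weeks (1007 higher and 964 lower in females) and 2756 at 12 weeks (1579 and 1177). Of these, 408 were higher and 351 lower in females on both diets at 2 weeks, where 54 and 42.9 are expected, and 588 and 337 at 12 weeks, where 88.9 and 37.4 are expected. At 2 weeks the count was 674 in a fit of these 6 libraries alone and 1282 without male 14. The larger share of higher genes at 2 weeks is not stable, with 1239 higher and 1339 lower by DESeq2, 318 and 356 in the 6 libraries alone, 674 and 818 without male 12 and 613 and 669 without male 14. The 12-week count was 1135 in a fit of the 6 libraries alone, 1742 without female 7 and 1651 without male 4.

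Diet was compared within each sex after 2 weeks to find the early liver response to high-fat feeding. In females cholesterol synthesis genes fell: Nsdhl, a sterol dehydrogenase (chromosome X, 72918557 to 72958514), went from 112 ± 16.3 CPM on RD to 33.5 ± 5.61 CPM on HFD (n = 3 each). Idi1 went from 363 ± 131 to 93.5 ± 13.4 CPM, and Mvd, a mevalonate pathway decarboxylase, from 19.8 ± 10.6 to 5.03 ± 1.23 CPM. Of the 25 members of the list 11 fell (23 adjusted over the list alone, 3 to 13 with 1 library left out, 0 in the groups alone), with a median of -1.38, camera adjusted p = 3.8e-35 and adjusted p = 0.027 with an estimated correlation. Pcx, the carboxylase that makes oxaloacetate, rose from 95.1 ± 10.7 to 230 ± 15.3 CPM. Cyp1a2 and Cyp3a44 had log2 fold changes of -1.34 ± 0.18 and -1.35 ± 0.19. Elovl6, a fatty acid elongase, fell from 187 ± 41.6 to 57.7 ± 11.3 CPM as the 1 called member of the 25 fatty acid synthesis genes (12 lower adjusted over the list alone, adjusted p = 0.42 with an estimated correlation). No fatty acid oxidation gene of 28 passed over all genes (9 higher adjusted over the list alone, median 0.52, camera adjusted p = 4.9e-12, adjusted p = 0.31 with an estimated correlation).

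In males at 2 weeks Me1, the malic enzyme that supplies NADPH (chromosome 9, 86581371 to 86695953), fell from 319 ± 21.6 CPM on RD to 73 ± 11.7 CPM on HFD (n = 3 each). Cyp3a11 fell from 1500 ± 244 to 437 ± 227 CPM. Part of the NRF2 response genes were lower in each sex, with Gstm3, a glutathione transferase, at -1.61 ± 0.3 in females and -1.81 ± 0.3 in males. The list of 18 had 2 called members in each sex (6 lower in females and 10 in males adjusted over the list alone, 0 to 2 and 1 to 3 with 1 library left out, 0 and 0 in the groups alone). Its camera adjusted p was 1.1e-05 and 3.9e-09, with adjusted p = 0.0048 and 0.00032 with an estimated correlation. Acute phase genes rose in males for 3 of 20 members (16 adjusted over the list alone, median 1.92, camera adjusted p = 5.2e-18, adjusted p = 0.19 with an estimated correlation). That count was 0 without HFD male 13 (median 1.01), 0 without RD male 6, 7 or 8, 9 without HFD male 12, 0 in the groups alone and 14 by DESeq2. The score of HFD male 13 was 10.28. Orm2 (chromosome 4, 63362449 to 63365878) had 256 ± 351 against 10.2 ± 3.54 CPM and Itih3 had 1840 ± 1340 against 594 ± 101 CPM. Ccnb2, a mitotic cyclin, fell by 1.54 ± 0.3 on the log2 scale as the 1 called member of the 20 cell cycle genes (7 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). No member was called without HFD male 13 or 14, without RD male 6, 7 or 8 or in the groups alone, and DESeq2 called 6. The counts by edgeR were 40 genes in females (5 higher and 35 lower on HFD) and 54 in males (19 and 35), and 4 were lower in both sexes, where 0.1 is expected. These 4, listed because their count was small and after their values were seen, were Gstm3, Tmem135, Gm11128 and Gm4477. The female count was 0 in a fit of the 6 libraries alone. It was 7, 14, 12 and 12 without HFD females 1 or 2 or RD females 1 or 2. In males it was 32 in a fit of the 6 libraries alone. It was 113, 12, 21, 25 and 23 without HFD males 12, 13 or 14 or RD males 6 or 8, and without HFD male 12 most were higher (68 higher and 45 lower).

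After 12 weeks the same comparison asks for the lasting liver response. In males part of the macrophage genes fell, and Csf1r went from 51.2 ± 6.26 CPM on RD to 17.8 ± 5.49 CPM on HFD (n = 3 each). Emr1 went from 18.4 ± 2.17 to 5.39 ± 1.46 CPM and the scavenger receptor Cd163 from 20.7 ± 5.78 to 5.82 ± 2.74 CPM. The drug-metabolising genes Cyp3a11 (chromosome 5, 145854426 to 145879964) and Ces2a fell from 2410 ± 461 to 415 ± 138 CPM and from 299 ± 52.6 to 105 ± 18.1 CPM. Arntl, a core clock activator, fell from 13.5 ± 6.92 to 2.67 ± 0.339 CPM. The scores of the circadian clock list overlapped between the diets. They were 4.71, 4.59 and 4.28 in RD males 2, 3 and 4 and 4.68, 5.01 and 4.08 in HFD males 2, 3 and 4. Among genes that rose, Pcx went from 76.7 ± 7.25 to 192 ± 34.9 CPM and the desaturase Fads2 from 639 ± 13.3 to 1260 ± 309 CPM. The secreted growth factor Nrg4 rose from 4.96 ± 0.609 to 27.7 ± 19 CPM and the lipid droplet protein Cidec from 5.98 ± 2.34 to 27.4 ± 23.6 CPM. Of 18 macrophage markers 4 fell (13 adjusted over the list alone, 2 to 6 with 1 library left out, 0 in the groups alone, median -0.78, camera adjusted p = 3e-13, adjusted p = 0.19 with an estimated correlation). Kupffer cell markers fell for 2 of 13 members (7 adjusted over the list alone, 0 to 5 with 1 library left out, 0 in the groups alone, adjusted p = 0.26 with an estimated correlation). Endothelial markers fell for 3 of 12 (7 adjusted over the list alone, 0 to 6 with 1 library left out, 0 in the groups alone, adjusted p = 0.14 with an estimated correlation), with Kdr at -1.06 ± 0.22. The macrophage scores were 2.84, 2.44 and 3.18 in HFD males 2, 3 and 4 and 3.73, 3.77 and 3.59 in RD males 2, 3 and 4.

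In females 1 gene passed at 12 weeks, Srp54b, a subunit of the signal recognition particle (chromosome 12, 55155104 to 55189573), at 26.9 ± 6.53 CPM on HFD and 57.5 ± 3.48 CPM on RD. No cholesterol synthesis gene passed over all genes in females (12 lower adjusted over the list alone, median -0.67, camera adjusted p = 4.3e-17, adjusted p = 0.16 with an estimated correlation). In males edgeR called 178 genes (32 higher and 146 lower on HFD), 6 of them lower at 2 weeks too, where 0.3 are expected. In females 686 genes had an unadjusted p under 0.05 and DESeq2 called 17. The male count was 0 in a fit of the 6 libraries alone. It was 353, 21, 47 and 90 without HFD males 2 or 3 or RD males 3 or 4. The female count was 0 without HFD female 3 or 7 or RD female 5, 7 or 8, in a fit of the 6 libraries alone, with median-of-ratios size factors and with no filter.

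**Figure D1:**
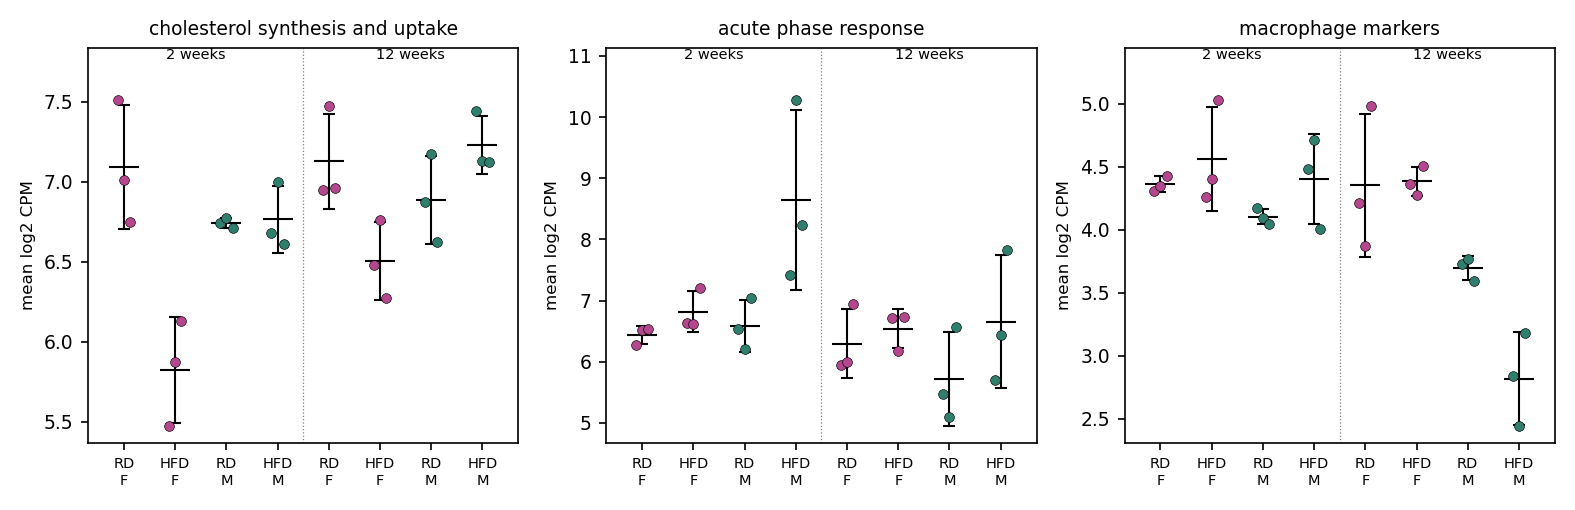
List scores of the 24 liver libraries: each point is the mean log2 CPM of a list's members in 1 library (vertical axis). Groups are set by diet and sex with 2 weeks left and 12 weeks right of the dotted line. Bars are the mean ± SD of 3. The cholesterol scores of HFD females at 2 weeks were 5.47, 5.87 and 6.13 beside 7.51, 7.01 and 6.75 on RD. The highest acute phase score was 10.28, and macrophage scores were at most 3.18 in HFD males at 12 weeks.

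Whether diet acts differently in the sexes was tested in liver by the sex by diet interaction. No single gene passed at either time by edgeR, with 1511 genes at an unadjusted p under 0.05 at 2 weeks and 1104 at 12 weeks. DESeq2 called 129 and 69. Cholesterol synthesis genes had a median interaction of -1.36 at 2 weeks and -1.09 at 12 weeks, a lower HFD over RD ratio in females. At 2 weeks the female scores of this list were 7.51, 7.01 and 6.75 on RD and 5.47, 5.87 and 6.13 on HFD. The male scores were 6.74, 6.77 and 6.71 on RD and 6.68, 7.00 and 6.61 on HFD. Of 25 members 20 and 12 were lower adjusted over the list alone and 0 over all genes (adjusted p = 0.11 and 0.16 with an estimated correlation). Acute phase genes had a median of -1.56 at 2 weeks with 12 of 20 lower adjusted over the list alone (adjusted p = 0.48 with an estimated correlation). Macrophage genes had 0.66 at 12 weeks with 3 of 18 higher adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). A sex index was taken per library, the mean log2 CPM of genes female-biased on RD in the other cohort minus that of the male-biased genes. It used 547 and 232 genes at 2 weeks and 512 and 254 at 12 weeks. The female minus male difference was 3.88 on RD and 3.70 on HFD at 2 weeks, and 3.80 and 3.60 at 12 weeks. Its interaction was -0.18 (p = 0.465) and -0.20 (p = 0.55) by a two-sided exact permutation test over 400 arrangements. The interaction count was 9, 4, 4, 2 and 5 at 2 weeks without HFD female 5, RD female 4, HFD male 12, HFD male 14 or RD male 7. It was 10, 2 and 1 at 12 weeks without HFD male 2, HFD male 4 or RD male 2. A fit of the 12 libraries of a time alone called 1 gene at 2 weeks and 1 at 12 weeks.

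**Figure D2:**
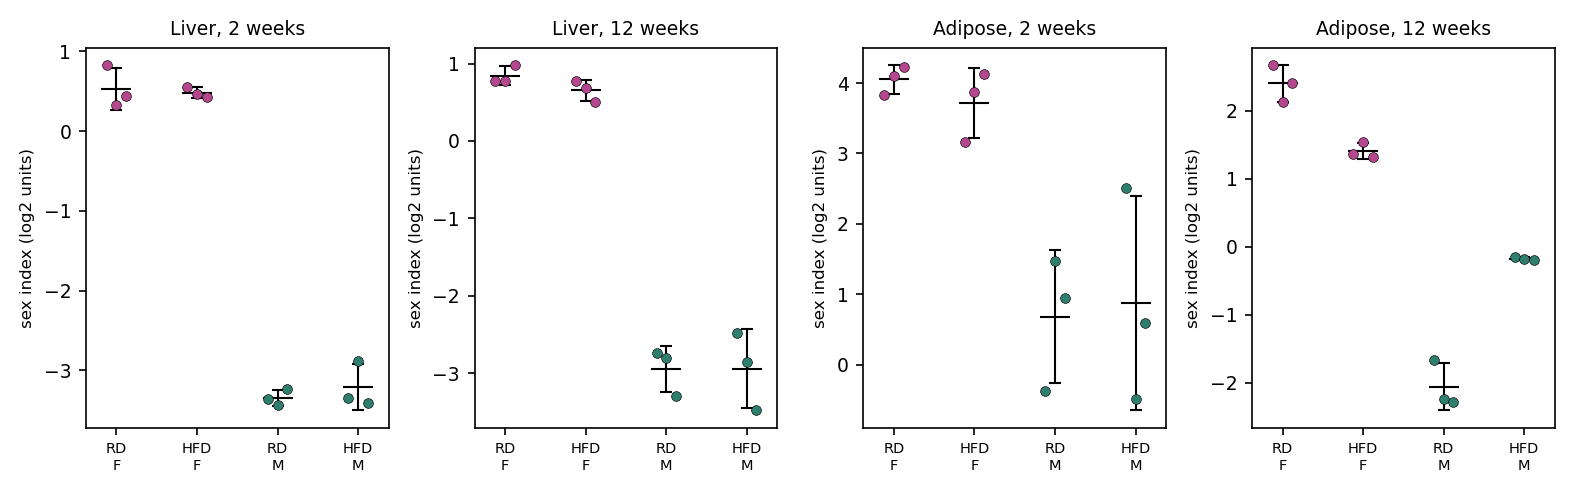
Sex index of each library (vertical axis, log2 units) by sex and diet for liver and adipose tissue at 2 and 12 weeks, with points for libraries and bars for the mean ± SD of 3. In adipose tissue at 12 weeks the female minus male difference was 4.46 on RD and 1.58 on HFD.

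In visceral white adipose tissue, females and males on RD were compared to find the transcripts that differ by sex without high-fat feeding. The labels do not say which visceral depot was taken in each sex, so a difference between depots is not separated from sex in any of the adipose comparisons of females with males. Hoxc10, a positional homeobox gene (chromosome 15, 102966796 to 102971893), had 33.6 ± 6.12 CPM in females and 0.841 ± 0.209 CPM in males at 2 weeks (n = 3 each). It had 25.1 ± 5.93 and 1.43 ± 0.756 CPM at 12 weeks. Sult1e1, the estrogen sulfotransferase (chromosome 5, 87575969 to 87591594), had 77.8 ± 15.3 CPM in males and 0.12 ± 0.0209 CPM in females at 2 weeks. Its log2 fold changes were -9.32 ± 0.51 and -9.87 ± 0.52 in the 2 cohorts. Hsd11b1, which activates glucocorticoids, was lower in females at 41.4 ± 5.57 against 213 ± 33.1 CPM at 2 weeks. Mest, an imprinted gene linked to adipocyte size, was lower at 17.9 ± 4.39 against 139 ± 12.2 CPM. The immunoglobulin genes Igha and Ighg2b were higher in females by 5.22 ± 0.95 and 6.28 ± 1.15 at 2 weeks. At 12 weeks Dio2, a thyroid hormone deiodinase, had 15.2 ± 6.61 CPM in females and 0.71 ± 0.0822 CPM in males. Elovl6 had 1460 ± 1070 and 107 ± 24.1 CPM, and the matrix protein Spon1 had 241 ± 77.7 and 17.7 ± 4.88 CPM. Mup20 and Mup7, which share reads with other Mup genes, had log2 fold changes of -9.6 ± 0.98 and -7.32 ± 0.85 at 12 weeks. Both were lower in females in liver too. Hepatocyte secreted protein scores of these adipose libraries were 3.58, 3.34 and 1.66 in RD females 5, 7 and 8. They were 5.82, 4.99 and 4.41 in RD males 2, 3 and 4, so the Mup differences are not separated from liver transcripts in the libraries.

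Progenitor markers Cd55 and Pi16 were higher in females in both cohorts, by 1.34 ± 0.22 and 1.74 ± 0.36 at 2 weeks. Of 18 list members 2 were higher at 2 weeks and 4 at 12 weeks (5 higher with 1 lower and 9 higher adjusted over the list alone, 1 to 2 and 2 to 7 with 1 library left out, adjusted p = 0.78 and 0.53 with an estimated correlation). Thermogenic markers were higher for 7 of 16 members at 2 weeks and 5 at 12 weeks, with 1 lower at 12 weeks (7 and 8 higher with 1 and 3 lower adjusted over the list alone, 0 to 7 and 2 to 4 higher with 1 library left out, adjusted p = 0.78 and 0.86 with an estimated correlation). The uncoupling protein Ucp1 had 36.2 ± 6.33 against 0.0272 ± 0.0472 CPM at 12 weeks. Muscle markers were higher in females at 2 weeks for 8 of 14 members (9 adjusted over the list alone, 0 to 9 with 1 library left out, adjusted p = 0.86 with an estimated correlation). Muscle scores were 2.98 and 3.87 in RD females 2 and 4 and -0.74 in RD female 1. The thermogenic scores of RD females 2, 4 and 1 were 3.63, 2.92 and 1.58. At 12 weeks 8 of 20 interferon genes (13 adjusted over the list alone, 0 to 9 with 1 library left out, adjusted p = 0.78 with an estimated correlation) and 7 of 25 matrix genes (11 adjusted over the list alone, 2 to 17 with 1 library left out, adjusted p = 0.78 with an estimated correlation) were higher in females. The interferon gene Oasl2 had 55.2 ± 30.4 against 15.9 ± 4.57 CPM and the matrix gene Lum 218 ± 41.3 against 59.1 ± 16.1 CPM. Epididymis markers were lower in females for 7 of 15 members at 2 weeks and 2 at 12 weeks (14 and 8 adjusted over the list alone, 0 to 9 and 0 to 7 with 1 library left out, adjusted p = 0.74 and 0.86 with an estimated correlation). With epithelial marker scores as covariates, a fit chosen after the data were seen, 0 progenitor, 0 thermogenic and 0 muscle markers were higher in females at 2 weeks. At 12 weeks 1 progenitor, 1 thermogenic, 0 interferon and 2 matrix genes were, so these list counts rest on the fit without covariates. The androgen-regulated reductase Akr1b7 had 11400 ± 18400 CPM in RD males at 12 weeks, with 1550, 9.22 and 32700 CPM in males 2, 3 and 4. Cyp11a1, a steroidogenic enzyme, was at 121 ± 208 CPM in RD females at 12 weeks, and its fold change without RD female 7 was -0.18. That library had an ovary, uterus and oviduct score of 2.70 beside 0.22 and 0.41.

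On RD edgeR called 785 of 18325 genes at 2 weeks (356 higher and 429 lower in females) and 1943 at 12 weeks (815 and 1128). Of these, 182 were higher and 255 lower in both cohorts where 15.8 and 26.4 are expected. With the epithelial covariates the counts were 233 and 208. Crisp1 was high in RD males 6 and 8 at 2 weeks and in RD males 2, 3 and 4 at 12 weeks. The overlap of genes lower in females is therefore not separated from tract tissue in both cohorts. The 2-week count was 322, 275, 241, 243, 514 and 487 without female 1, 2 or 4 or male 6, 7 or 8, and DESeq2 called 1986. Without a female more genes were higher than lower in females (199 and 123, 175 and 100, and 146 and 95 without female 1, 2 or 4). The 12-week count was 485, 870, 438, 4520, 623 and 506 without female 5, 7 or 8 or male 2, 3 or 4, 1273 with no filter and 3857 by DESeq2. Without female 5, 7 or 8 more genes were higher than lower in females (294 and 191, 530 and 340, and 247 and 191), while the 6 libraries alone gave 233 higher and 1230 lower.

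Females and males on HFD were compared next in adipose tissue. At 2 weeks Dio2 (chromosome 12, 90724552 to 90738438) had 65.4 ± 41.9 CPM in females and 0.601 ± 0.107 CPM in males (n = 3 each). The cytochrome oxidase subunit Cox8b had 39.3 ± 15.6 and 4.04 ± 1.84 CPM, and the coactivator Ppargc1a 46 ± 29.6 and 6.23 ± 2.61 CPM. Of 16 thermogenic markers 10 were higher in females (11 adjusted over the list alone, 3 in the groups alone, median 3.22, camera adjusted p = 1.2e-15, adjusted p = 0.095 with an estimated correlation). The thermogenic scores were 4.55, 3.59 and 4.77 in HFD females 1, 2 and 5 and 0.39, 0.99 and 1.39 in HFD males 12, 13 and 14. The muscle scores of these females were 0.46, -0.28 and 2.61, and female 1 is the library with the adipocyte score of 8.34. Of 14 muscle markers 2 were higher in females (5 adjusted over the list alone, 0 to 3 with 1 library left out, 0 in the groups alone, 0 with the epithelial covariates, adjusted p = 0.875 with an estimated correlation). The Wnt inhibitor Sfrp5 was lower at 6.65 ± 4.71 against 144 ± 34 CPM, and the macrophage elastase Mmp12 at 1.87 ± 0.67 against 38.2 ± 8.73 CPM. At 12 weeks Mmp12 (chromosome 9, 7344381 to 7369499) had 47.3 ± 38.6 CPM in females and 1220 ± 378 CPM in males. The lipid-associated macrophage gene Gpnmb had 40.5 ± 38 and 1000 ± 507 CPM, the integrin Itgax 18.1 ± 4.43 and 220 ± 86.2 CPM, and the interleukin receptor Il7r 7.07 ± 1.59 and 77.7 ± 14.8 CPM. Lipid-associated macrophage markers were lower in females for 8 of 16 members (12 adjusted over the list alone, 13 in the groups alone, median -1.86, camera adjusted p = 1.2e-15, adjusted p = 0.014 with an estimated correlation). Macrophage markers were lower for 6 of 18 (12 adjusted over the list alone, 3 to 6 with 1 library left out, 11 in the groups alone, median -0.94, camera adjusted p = 2.3e-11, adjusted p = 0.28 with an estimated correlation). Hoxc10, Hoxa10 and Hoxa9 were higher in females by 6.75 ± 0.52, 6.5 ± 1.24 and 5.8 ± 0.6, and Pgr, the progesterone receptor, by 7.32 ± 1.21. HFD female 3 had a pancreas acinar score of 2.33, beside -2.25 and -1.95 in HFD females 6 and 7. Of 13 acinar markers 1 was higher in females (11 adjusted over the list alone, 0 to 3 with 1 library left out, 2 with the epithelial covariates, adjusted p = 0.86 with an estimated correlation).

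On HFD edgeR called 696 genes at 2 weeks (366 higher and 330 lower in females) and 522 at 12 weeks (190 and 332). On both diets 137 were higher and 138 lower in females at 2 weeks, where 7.1 and 7.7 are expected, and 82 and 37 at 12 weeks, where 8.5 and 20.4 are expected, with 9 genes going opposite ways. At 2 weeks the count was 423, 250 and 353 without female 1, male 13 or male 14, 28 in a fit of the 6 libraries alone, 1918 by DESeq2 and 220 with the epithelial covariates. The even balance of directions is not stable. It was 488 higher and 162 lower without female 2, 400 and 199 without female 5, 226 and 690 without male 12, 121 and 232 without male 14 and 830 and 1088 by DESeq2. The 12-week count was 271, 259, 280 and 210 without female 3, 6 or 7 or male 4, 1167 in a fit of the 6 libraries alone and 1174 by DESeq2.

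Diet was compared within each sex after 2 weeks for the early response of adipose tissue. In females Insig1, a brake on sterol synthesis (chromosome 5, 28071363 to 28078662), fell from 400 ± 13.3 CPM on RD to 114 ± 43.7 CPM on HFD (n = 3 each). The elongase Elovl5 fell from 310 ± 74.5 to 141 ± 31 CPM. Dio2 rose from 7.11 ± 4.99 to 65.4 ± 41.9 CPM and Ppargc1a from 7.34 ± 4.06 to 46 ± 29.6 CPM. Cpt1a, which admits fatty acids to mitochondria, rose from 62.5 ± 7.9 to 126 ± 13.8 CPM. Fatty acid synthesis genes fell for 1 of 25 members (17 adjusted over the list alone, 0 to 7 with 1 library left out, median -1.25, camera adjusted p = 7.8e-12, adjusted p = 0.53 with an estimated correlation). Cholesterol genes fell for 1 of 25 (18 lower and 1 higher adjusted over the list alone, 0 to 8 lower with 1 library left out, adjusted p = 0.67 with an estimated correlation), and oxidative phosphorylation genes for 0 of 27 (16 lower adjusted over the list alone, median -0.66, adjusted p = 0.78 with an estimated correlation). HFD female 1, with the low adipocyte score, is part of this comparison. In males no gene passed by edgeR, with 2022 at an unadjusted p under 0.05 and 130 called by DESeq2. Male oxidative phosphorylation genes had a median of -0.64 with 19 of 27 lower adjusted over the list alone (camera adjusted p = 1.3e-15, adjusted p = 0.67 with an estimated correlation). Fatty acid synthesis genes had -0.71 with 9 of 25 lower adjusted over the list alone (adjusted p = 0.67 with an estimated correlation). The edgeR count in females was 43 (18 higher and 25 lower). The 2-week interaction called 0 genes by edgeR, with 1246 at an unadjusted p under 0.05 and 72 by DESeq2. The female count was 11, 1212, 617, 14, 3 and 3 without HFD females 1, 2 or 5 or RD females 1, 2 or 4. It was 0 in a fit of the 6 libraries alone, 12 with no filter, 1504 by DESeq2 and 28 with the epithelial covariates. Most genes were then higher on HFD without HFD female 2 (821 higher and 391 lower), without HFD female 5 (491 and 126) and by DESeq2 (850 and 654). Of the 43 genes 6 were called again without HFD female 1, and 3 each without RD female 2 or 4. Without RD male 6, 7 or 8 the male count was 1, 6 and 10, and with the epithelial covariates 24.

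After 12 weeks males had the highest number of diet-responsive genes among the 20 contrasts. Macrophage genes rose: Mmp12 went from 20.3 ± 14.6 CPM on RD to 1220 ± 378 CPM on HFD (n = 3 each). Gpnmb (chromosome 6, 49036546 to 49070929) rose by 5.78 ± 0.91. Itgax (chromosome 7, 128129547 to 128150657) rose from 6.67 ± 4.25 to 220 ± 86.2 CPM. The lysosomal proteins Cd68 and Ctss rose from 25.2 ± 5.97 to 285 ± 89.6 CPM and from 71.1 ± 7.65 to 639 ± 106 CPM. Lep, the satiety hormone leptin (chromosome 6, 29060220 to 29073877), singled out after its values were seen, rose from 982 ± 126 to 3380 ± 179 CPM. The imprinted gene Mest rose from 130 ± 29.8 to 768 ± 108 CPM. Cfd, the adipocyte protease adipsin, fell from 4010 ± 1200 to 557 ± 116 CPM. The desaturases Fads1 and Fads2 fell from 224 ± 94.6 to 57.1 ± 3.08 CPM and from 301 ± 269 to 17.7 ± 3.42 CPM. Of 18 macrophage markers 15 rose (15 adjusted over the list alone, median 1.51, camera adjusted p = 2.3e-11, adjusted p = 0.28 with an estimated correlation). Of 16 lipid-associated macrophage markers 9 rose (11 adjusted over the list alone, median 2.45, camera adjusted p = 5.2e-09, adjusted p = 0.095 with an estimated correlation). Matrix genes rose for 21 of 25 members (23 adjusted over the list alone, median 1.62, adjusted p = 0.67 with an estimated correlation), with the collagen Col6a1 from 285 ± 161 to 1150 ± 69.9 CPM. Cell cycle genes rose for 17 of 20 (18 adjusted over the list alone, median 1.89, adjusted p = 0.67 with an estimated correlation), with the proliferation antigen Mki67 from 6.72 ± 4.8 to 62.1 ± 16.9 CPM. Il7r (chromosome 15, 9505788 to 9530176) rose from 3.87 ± 0.821 to 77.7 ± 14.8 CPM.

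Oxidative phosphorylation genes fell for 15 of 27 members in these males (19 adjusted over the list alone, 3 to 20 with 1 library left out, 4 in the groups alone, median -0.69, camera adjusted p = 1.8e-05, adjusted p = 0.87 with an estimated correlation). Cox6c fell from 390 ± 308 to 108 ± 12.1 CPM. The list scores were 6.8, 7.33 and 7.66 in RD males 2, 3 and 4, in the order of their ribosomal protein share of 1.92, 2.91 and 5.85% of counts. In HFD males 2, 3 and 4 the scores were 6.61, 6.38 and 6.55 and the shares 1.81, 1.77 and 1.92%, so the fall of this list is not separated from that difference between libraries. Epithelial and tract markers fell too, among them 4 of 15 epididymis markers (6 adjusted over the list alone, 0 to 2 with 1 library left out, 7 in the groups alone, adjusted p = 0.88 with an estimated correlation). The falls took in 6 of 9 mammary epithelium markers (8 adjusted over the list alone, 1 to 6 with 1 library left out, adjusted p = 0.84 with an estimated correlation) and 7 of 12 mesothelial markers (7 adjusted over the list alone, 1 to 6 with 1 library left out, 4 in the groups alone, 1 with the epithelial covariates, adjusted p = 0.86 with an estimated correlation). Cdh1 fell from 46.7 ± 4.07 to 0.231 ± 0.067 CPM and Krt8 from 104 ± 43 to 7.32 ± 8.94 CPM. The epididymis scores were 1.06, 1.39 and 0.77 in RD males 2, 3 and 4 and -2.87, -2.98 and -3.49 in HFD males 2, 3 and 4. With the epithelial covariates, chosen after the data were seen, 12 macrophage, 10 lipid-associated macrophage, 14 cell cycle and 7 matrix markers were higher, of which 12, 9, 13 and 6 were among those called without covariates. Of the oxidative phosphorylation genes 3 were lower, all called without covariates too. The highest count by edgeR was 5168 genes (2416 higher and 2752 lower on HFD). It was 3075 in a fit of the 6 libraries alone, 2549 with the animal number as a block and 1693 with the epithelial covariates (988 and 705). The median of all log2 fold changes was -0.112. The count was 3309, 3413, 2420, 3394 and 2851 without HFD males 2, 3 or 4 or RD males 3 or 4. More genes rose than fell without HFD male 2 (1876 and 1433), 3 (1868 and 1545) or 4 (1398 and 1022) or RD male 4 (1449 and 1402).

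**Figure D3:**
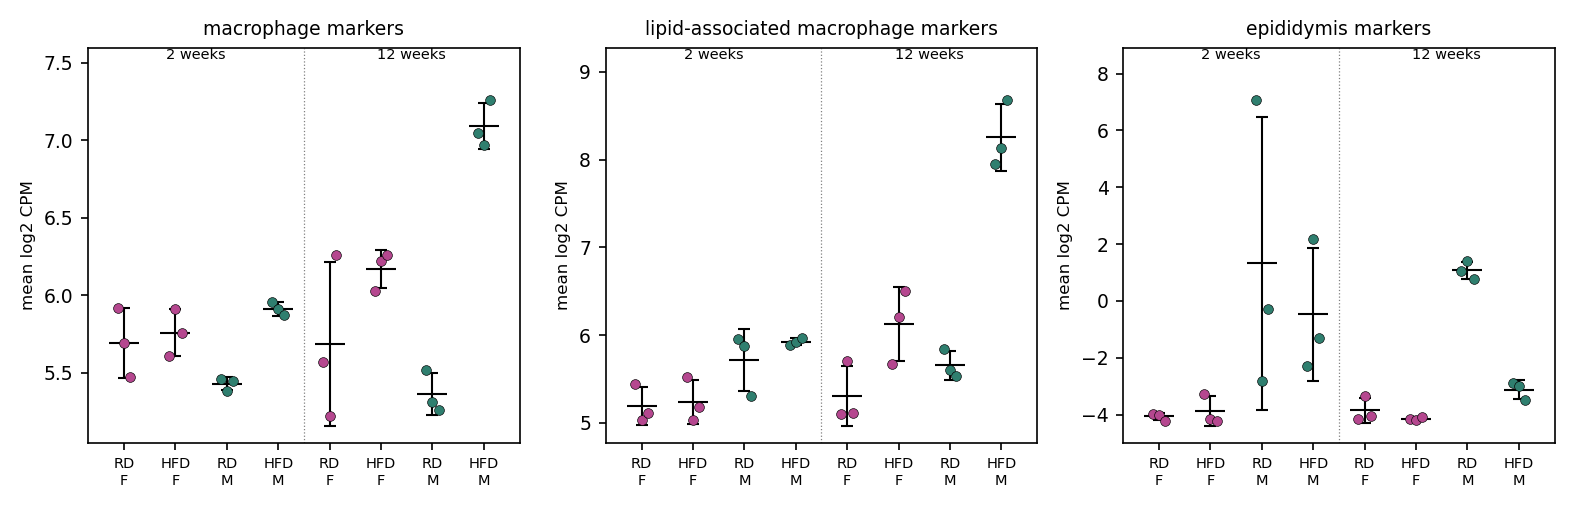
List scores of the 24 adipose libraries: each point is the mean log2 CPM of a list's members in 1 library (vertical axis). Groups are set by diet and sex with 2 weeks left and 12 weeks right of the dotted line. Bars are the mean ± SD of 3. Lipid-associated macrophage scores were 7.95, 8.13 and 8.68 in HFD males at 12 weeks and at most 6.5 in HFD females at 12 weeks. The highest epididymis score was 7.07 in RD male 6 at 2 weeks.

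In females at 12 weeks diet was compared in the same way. Sfrp5 (chromosome 19, 42197971 to 42202252) went from 3.85 ± 1.96 CPM on RD to 241 ± 120 CPM on HFD (n = 3 each). Mest (chromosome 6, 30723547 to 30748465) rose from 17.6 ± 5.97 to 987 ± 126 CPM and Lep from 272 ± 83.3 to 2730 ± 475 CPM. The natriuretic peptide clearance receptor Npr3 rose from 327 ± 75.3 to 1310 ± 27.9 CPM. The transcription factor Klf14 rose from 0.926 ± 0.163 to 23 ± 5.54 CPM. Part of the fatty acid synthesis genes fell, with the acetyl-CoA carboxylases Acaca and Acacb going from 4220 ± 2230 to 629 ± 186 CPM and from 405 ± 130 to 78.9 ± 12.2 CPM. Elovl6 fell from 1460 ± 1070 to 133 ± 101 CPM. Acsm3, a mitochondrial acyl-CoA ligase, fell from 123 ± 61.6 to 12.7 ± 3.13 CPM. Of 17 adipokines 4 rose (5 higher and 2 lower adjusted over the list alone, median 1.00, camera adjusted p = 0.00097, adjusted p = 0.78 with an estimated correlation). Of 25 fatty acid synthesis genes 4 fell (11 adjusted over the list alone, 0 to 8 with 1 library left out, median -1.08, adjusted p = 0.78 with an estimated correlation). The scores of that list were 8.75, 8.96 and 7.31 in RD females 5, 7 and 8. In HFD females 3, 6 and 7 they were 7.23, 7.87 and 7.02. Matrix genes rose for 3 of 25 members (8 adjusted over the list alone, 1 to 3 with 1 library left out, 10 in the groups alone, adjusted p = 0.74 with an estimated correlation), with the matrix glycoprotein Sparc from 1950 ± 136 to 5380 ± 264 CPM. No macrophage marker of 18 passed over all genes or adjusted over the list alone (median 0.45, camera adjusted p = 0.00026, adjusted p = 0.78 with an estimated correlation). Mmp12 rose from 5.59 ± 4.01 to 47.3 ± 38.6 CPM as the 1 called lipid-associated macrophage gene (3 adjusted over the list alone, 0 to 1 with 1 library left out, 3 with the epithelial covariates, adjusted p = 0.5 with an estimated correlation). Markers of other tissues moved here too, with 2 of 14 ovary, uterus and oviduct markers lower and 1 of 13 acinar markers higher on HFD. RD female 7 had an ovary, uterus and oviduct score of 2.70, beside 0.22 and 0.41 in RD females 5 and 8. HFD female 3 had an acinar score of 2.33, beside -2.25 and -1.95 in HFD females 6 and 7.

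In these females edgeR called 381 genes (239 higher and 142 lower on HFD), 749 in a fit of the 6 libraries alone, 1002 by DESeq2 and 624 with the epithelial covariates. It was 189, 162, 138, 92 and 151 without HFD females 3, 6 or 7 or RD females 5 or 7. Of the called genes 151 rose and 74 fell in both sexes at 12 weeks, where 31.5 and 21.3 are expected, and 3 went opposite ways. Among them, named because so few were found and after their values were seen, were C6 and Serpina3b. Dio2 and Ppargc1a, higher on HFD in females at 2 weeks, were lower at 12 weeks, with log2 fold changes of -2.47 ± 0.59 and -2.07 ± 0.49. Their 2-week calls belong to a set of 43 genes, of which 6 were called again without HFD female 1.

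The sex by diet interaction at 12 weeks asks which adipose genes respond to diet differently in females and males. Il7r had an interaction of -4.02 ± 0.42, with 5.73 ± 1.82 CPM on RD and 7.07 ± 1.59 on HFD in females beside the 20-fold rise in males. The macrophage genes Itgax, Ctss and Cd68 had -3.49 ± 0.6, -2.5 ± 0.34 and -2.54 ± 0.48. Sfrp5 and Mest had 3.55 ± 0.7 and 3.25 ± 0.63, a larger rise in females. Of 16 lipid-associated macrophage markers 5 had a lower HFD effect in females (9 adjusted over the list alone, 3 to 8 with 1 library left out, median -2.02, camera adjusted p = 1.2e-07, adjusted p = 0.15 with an estimated correlation). Of 18 macrophage markers 4 had a lower effect (11 adjusted over the list alone, 2 to 7 with 1 library left out, median -1.12, camera adjusted p = 9.6e-10, adjusted p = 0.42 with an estimated correlation). With the epithelial covariates 5 and 3 members passed, 4 and 3 of them called without covariates too. For this interaction edgeR called 229 genes (54 positive and 175 negative), 941 in a fit of the 12 libraries alone, 1364 by DESeq2 and 124 with the epithelial covariates. With the animal number of the males as a block, a fit chosen after the data were seen, it called 830. The larger share of negative genes does not hold in all fits, with 659 positive and 282 negative in the 12 libraries alone, 595 and 235 with the block and 694 and 670 by DESeq2. It was 85, 99, 123, 124, 84, 50, 894, 79 and 100 without HFD females 3, 6 or 7, RD females 5 or 8, HFD male 4 or RD males 2, 3 or 4.

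The adipose sex index, built from 264 female-biased and 376 male-biased genes of the 2-week RD cohort, was 2.40 ± 0.27 in RD females, 1.41 ± 0.113 in HFD females, -2.06 ± 0.347 in RD males and -0.17 ± 0.026 in HFD males at 12 weeks (n = 3 each). The female minus male difference was 4.46 on RD and 1.58 on HFD, an interaction of -2.88, with p = 0.005 by a two-sided exact permutation test, the smallest p its 400 arrangements gave. With diet exchanged only within the 3 pairs of males that share an animal number, a test chosen after the data were seen, the exact permutation p was 0.0125, the smallest its 160 arrangements allow. Both permutation tests of the interaction are exact only where diet has no effect in either sex. Within each sex the diet difference had an exact permutation p = 0.1, the smallest that 3 against 3 allow. The RD males of the 2-week cohort that define the male-biased genes include male 6, with its epididymis score of 7.07. Female-biased genes alone gave an interaction of -0.66 and male-biased genes alone -2.22. The HFD minus RD difference of the index was -0.994 in females and 1.885 in males. In the males compared the epididymis scores were 1.06, 1.39 and 0.77 on RD and -2.87, -2.98 and -3.49 on HFD. The male part of the index change is therefore not separated from a loss of tract tissue. In the females these scores were low on both diets, at -4.14, -3.35 and -4.06 on RD and -4.15, -4.20 and -4.08 on HFD. At 2 weeks the interaction was -0.53 with p = 0.645 by the same permutation test.

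**Figure D4:**
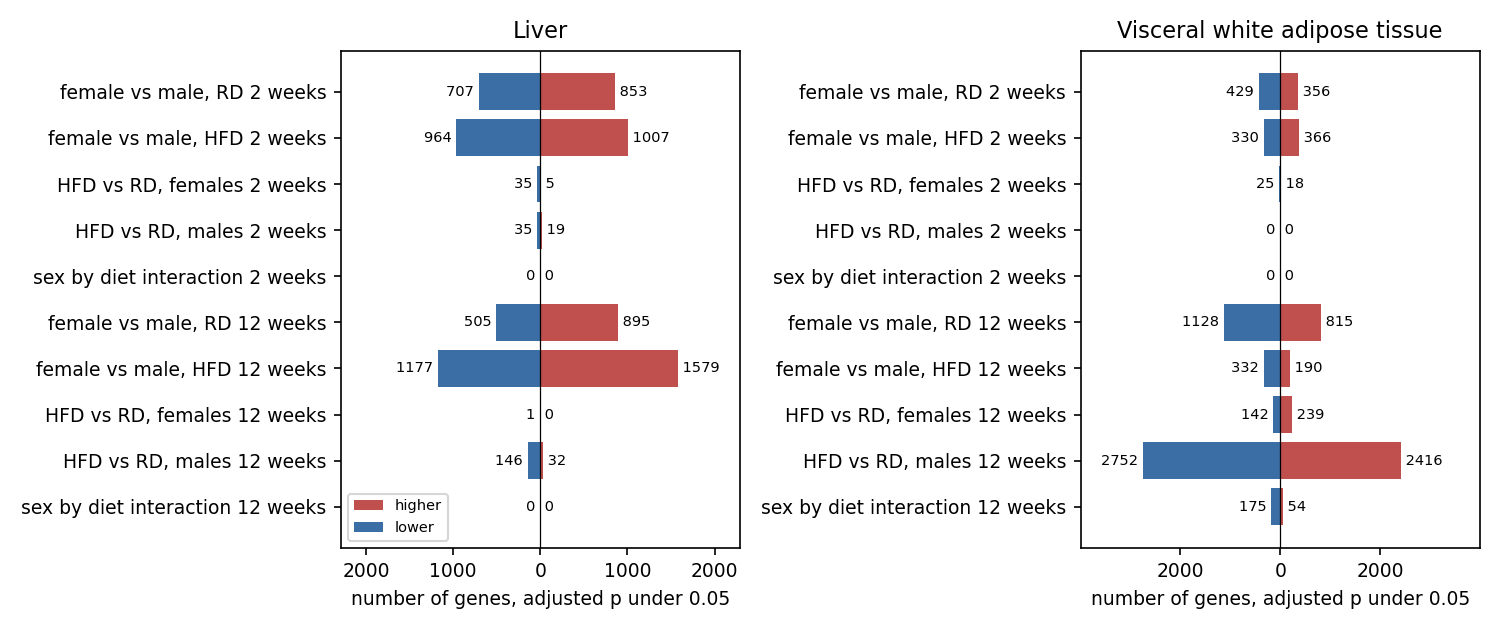
Number of genes called by edgeR in each of the 10 contrasts per tissue (horizontal axis), with genes higher in the first group or positive in the interaction to the right and lower or negative to the left. Liver counts between the sexes ran from 1400 to 2756, and the highest count was 5168 for diet in males after 12 weeks in adipose tissue.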

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

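The quartile tests of dilution in adipose tissue, the quartile comparison in liver, the rank correlations, the fit with epithelial covariates, the blocked interaction and the comparisons of splits by pairs and by whole groups were chosen only after the results were seen. The first results compare the response to diet between the sexes, as interaction calls with their list medians and genes. None of the list medians holds with an estimated correlation.

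In adipose tissue at 12 weeks the interaction called 229 genes (54 positive and 175 negative, and 595 and 235 of 830 with the animal number of the males as a block). The sex index had an interaction of -2.88. In its male part, a change of 1.885, a loss of tract tissue in HFD males is not separated from diet. The list medians were -2.02 for lipid-associated macrophage markers and -1.12 for macrophage markers (adjusted p = 0.15 and 0.42 with an estimated correlation). The genes named by rule include Kcnj16 (6.82), Hoxa10 (6.17), Mup20 (6.04), Dhrs9 (-5.38) and Il7r (-4.02). Hepatocyte secreted protein scores at 12 weeks were 2.35, 6.11 and 4.55 in HFD females and 3.49, 4.39 and 2.93 in HFD males. On RD they were 3.58, 3.34 and 1.66 in females and 5.82, 4.99 and 4.41 in males. The value of Mup20 is not separated from these differences between libraries. At 2 weeks thermogenic markers had a median interaction of 1.83 in adipose tissue (adjusted p = 0.245 with an estimated correlation). In liver at 2 weeks the medians were 0.87 for cell cycle genes, -1.36 for cholesterol synthesis and 0.59 for lipid droplet genes (adjusted p = 0.11, 0.11 and 0.1 with an estimated correlation). At 12 weeks they were -1.09 for cholesterol synthesis and 0.47 for endothelial markers (adjusted p = 0.16 and 0.15 with an estimated correlation). The liver lists had no member called over all genes by edgeR, with 1511 and 1104 genes at an unadjusted p under 0.05 at 2 and 12 weeks and 129 and 69 called by DESeq2.

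Genes lower on HFD in male adipose tissue at 12 weeks go with markers of reproductive tract epithelium, which were high in the 3 RD libraries. Members of the epididymis, mammary epithelium and sex chromosome lists and Y-linked genes were left out of the gene sets called or not called. Across the 6 male libraries at 2 weeks, centred by group, the 2742 lower genes that remained had a median correlation with the epididymis score of 0.521 (Spearman 0.6, and 0.601 without RD male 6), while 13126 uncalled genes had 0.039. Tract tissue dissected along with the fat of RD males may therefore account for part of these falls. The 54 genes with a positive interaction had 0.467 (Spearman 0.486, and 0.615 without RD male 6), which leaves their source open. An effect of the diet on these genes stays open as untested.

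In the same males 15 of 18 macrophage markers rose on HFD. Less tract tissue in the HFD libraries would raise all other transcripts alike. The 175 genes with a negative interaction had a median correlation with the epididymis score of -0.755, which met the prediction written for dilution beforehand. Dilution may therefore account for part of the rise of these genes. The macrophage list had -0.66 (Spearman -0.657, and -0.488 without RD male 6). Lipid-associated macrophage markers had 0.291 (Spearman 0.2, and -0.222 without RD male 6), a sign that turns with 1 library and decides nothing for that list. For the markers on the fixed macrophage list the lower quartile was 1.17, above the upper quartile of adipocyte genes at 0.421, which argues against dilution as the whole cause of their rise. The lower quartile of the lipid-associated macrophage list was 0.893, above the same value, which argues the same way for that list. With the epithelial covariates 12 of the 15 called macrophage markers and 9 of the 9 called lipid-associated ones were called again. More macrophages, more transcript per cell and an effect of diet through either stay open.

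In male liver at 12 weeks 4 of 18 macrophage and 2 of 13 Kupffer cell markers fell on HFD, and the list medians were -0.78 and -0.90 (adjusted p = 0.19 and 0.26 with an estimated correlation). A lower share of all cells other than hepatocytes would lower the markers of each such type alike. The upper quartile of the macrophage list was -0.553, and the lower quartiles of the stellate and endothelial lists were -0.56 and -0.835, so their ranges overlap with it. The medians of these 2 lists were -0.241 and -0.424, smaller falls than the macrophage median. The bile duct list had a lower quartile of -0.37, but its mean log2 CPM of 0.63 is near the floor and excludes nothing. A lower share of these cells and a change in macrophages themselves therefore cannot be told apart here, and the diet itself stays open.

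Other splits of the same libraries were counted for each contrast. With 3 against 3 there are 10 splits, too few for a share under 0.05. In liver 1 of 10 splits, the real one, reached the real count in sex on RD at 2 weeks (1560, highest other 1), sex on HFD at 2 weeks (1971, highest other 305), diet in females (40, highest other 2) and males (54, highest other 6) at 2 weeks. The same held at 12 weeks for sex on RD (1400, highest other 0), sex on HFD (2756, highest other 1) and diet in males (178, highest other 9). For diet in females at 12 weeks 2 of 10 splits gave as many (1, highest other 3). In adipose tissue 1 of 10 splits reached the real count in sex on RD (785, highest other 0) and diet in females (43, highest other 1) at 2 weeks, and at 12 weeks in sex on RD (1943, highest other 0), sex on HFD (522, highest other 0), diet in females (381, highest other 0) and diet in males (5168, highest other 1). Of the 4 splits that part the 3 pairs of male animal numbers, 1, the real one, reached 5168 (highest other 0), and the 6 splits that part fewer pairs gave at most 1. For sex on HFD at 2 weeks 2 of 10 splits gave as many (696, highest other 1734). Another grouping of these libraries thus gave more calls than sex, and what it follows was not tested. Diet in males at 2 weeks had 0 genes by edgeR (2022 at an unadjusted p under 0.05, 130 by DESeq2). All 10 of 10 splits gave as many, which a real count of 0 fixes in advance. The highest other was 234, and what that split follows was not tested.

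For the interaction 40 splits were drawn. In liver 40 of 40 gave at least the real 0 at 2 weeks (highest other 10) and at 12 weeks (highest other 33), and in adipose tissue 40 of 40 at 2 weeks (highest other 277). A real count of 0 fixes these shares in advance, and what the splits with calls follow was not tested. These counts of 0 are from edgeR, with 1511, 1104 and 1246 genes at an unadjusted p under 0.05 and 129, 69 and 72 by DESeq2. In adipose tissue at 12 weeks 4 of 40 splits gave as many as the real 229, with a highest other of 2300. By this share chance was not excluded for this count. Of the 16 splits that part the 3 male pairs 4 gave as many, and of the 24 that part fewer pairs 0 did (highest 33). The 3 other splits as large keep the male diet groups whole, so they hold the male diet difference. The share of 4 of 40 therefore does not measure chance alone and cannot decide for or against it. The splits that keep neither sex whole gave at most 0.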

How the results depend on the processing

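The fit with epithelial covariates, the interaction with the animal number of males as a block and the sex index with exchanges within male pairs were chosen after the data were seen, and the other alternatives were planned. The cause of a change between settings was not tested. In a fit of the compared groups alone liver counts were 2965 for sex on RD at 2 weeks, 674 and 1135 for sex on HFD at 2 and 12 weeks, 0 and 32 for diet in females and males at 2 weeks, 0 and 0 at 12 weeks, and 1 and 1 for the interactions. In adipose tissue they were 28 and 1167 for sex on HFD at 2 and 12 weeks, 0 and 749 for diet in females, 3075 for diet in males at 12 weeks and 941 for the interaction at 12 weeks. With no filter liver gave 25 and 0 genes for diet in females at 2 and 12 weeks and 1 for the interaction at 2 weeks, and adipose tissue 12 for diet in females at 2 weeks and 1273 for sex on RD at 12 weeks. Median-of-ratios size factors gave 0 for diet in liver of females at 12 weeks, where edgeR had 686 genes at an unadjusted p under 0.05 and DESeq2 called 17. DESeq2 called more in liver for diet in females and males at 2 weeks (180 and 326), diet in males at 12 weeks (451) and the interactions (129 and 69). In adipose tissue it called 1986 and 1918 for sex on RD and HFD at 2 weeks, 1504 and 130 for diet in females and males, 72 for the interaction, and at 12 weeks 3857 and 1174 for sex, 1002 for diet in females and 1364 for the interaction. With the replicate number as a block liver gave 109 for diet in females at 2 weeks and 0 for diet in males at 12 weeks, and adipose tissue 0 for diet in females at 2 weeks and 2549 for diet in males at 12 weeks. Only for the last of these blocks did all libraries with a shared number correlate best with each other. What a shared number stands for is not known, so a pairing is not established. With the animal number of the males as a block the adipose interaction at 12 weeks called 830.

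With the epithelial covariates adipose counts were 233 and 220 for sex on RD and HFD at 2 weeks, 28 and 24 for diet in females and males, 1 for the interaction, and at 12 weeks 208 for sex on RD, 624 and 1693 for diet in females and males and 124 for the interaction. Of the 1693 genes 1408 were among the 5168 called without covariates. These covariates differ between the groups compared, so a fit with them can take out a diet or sex difference as well. The sex index of female-biased genes alone had an interaction of -0.21 in liver at 2 weeks with an exact permutation p = 0.02, and the other gene choices and settings of the index there gave p from 0.1 to 0.835. With each library left out in turn counts ran in liver from 779 to 1099 (sex on RD), 1282 to 2040 (sex on HFD), 7 to 36 and 12 to 113 (diet in females and males) and 0 to 9 (interaction) at 2 weeks. At 12 weeks they ran from 706 to 1127, 1651 to 3247, 0 to 1, 21 to 353 and 0 to 10 in the same order. In adipose tissue they ran from 241 to 514, 250 to 916, 3 to 1212, 0 to 10 and 0 to 0 at 2 weeks, and from 438 to 4520, 210 to 403, 92 to 305, 2420 to 6472 and 50 to 894 at 12 weeks.

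Of the list calls, 110 of 320 in liver and 128 of 360 in adipose tissue passed with the preset correlation, 11 and 1 with an estimated correlation and 61 and 29 with fry. Genes changed by diet the same way in both sexes numbered 4 in liver at 2 weeks and 225 in adipose tissue at 12 weeks. They were 10 and 403 at an adjusted p under 0.1, and 137 in adipose tissue with an absolute log2 fold change of at least 1. Calls of named genes were lost in 1476 of 4722 fits with 1 library left out, 277 of 759 in the compared groups alone, 107 of 768 with no filter, 181 of 377 with the covariates, 76 of 169 with the replicate block and 2 of 19 with the males blocked. DESeq2 gave an adjusted p for 757 calls and lost none of them. Calls without one, among them those of Rnase10, Adam28, Klrb1c, Ovgp1 and Cyp11a1 below, were not counted there. Of 768 calls 4 were lost with the size factors and 2 with robust FALSE. These losses include a reversed direction in 5 fits with 1 library left out and 5 with the covariates. For sex on RD in adipose tissue at 2 weeks Rnase10 ran from -8.71 (without RD female 1) to 1.09 (without RD male 6) and was 2.57 with the covariates, where Adam28 was 2.09 and Klrb1c 0.42. For sex on HFD at 2 weeks Ovgp1 ran from -0.38 (without HFD female 1) to 4.70 (without HFD female 2). Cyp11a1 at 12 weeks ran from -0.18 (without RD female 7) to 7.38 (without RD female 5) for sex on RD, and from -7.39 (without RD female 5) to 0.18 (without RD female 7) for diet in females. For diet in males at 12 weeks Cd8a ran from -0.10 (without HFD male 3) to 2.20 (without HFD male 4), and with the covariates Elf5 was 0.55 and Krt5 1.00.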

Other observations

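The values in this part were singled out after the data were seen, and none was tested for its source. Some immunoglobulin genes differed between the sexes, and no list of these genes alone was tested. In liver the sex difference of Igj was 3.63 on RD and 3.71 on HFD at 2 weeks. In adipose tissue it was 3.11 and 3.04 at 2 weeks. The adipose B cell scores on RD at 12 weeks were 1.65, 1.75 and 2.06 in females and 2.2, 1.91 and 2.53 in males. In adipose tissue Igha had 227 ± 80.8 CPM in RD females and 6.11 ± 7.73 CPM in RD males at 2 weeks (n = 3 each), and a log2 fold change of 7.42 ± 1.06 on HFD. In liver Igha had a log2 fold change of -2.93 ± 0.50 between HFD and RD in males at 12 weeks, with Igj at -1.87 ± 0.35.

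Heat shock scores at 12 weeks were highest in each tissue in the male libraries numbered 4. The liver score was 5.12 in RD male 4 beside 3.64 and 3.95 in RD males 2 and 3. On HFD it was 5.73 beside 3.80 and 4.25 in HFD males 2 and 3, and the adipose score was 6.66 beside 5.62 and 5.42. RD male 4 had an adipose score of 6.58 beside 5.56 and 5.24 in RD males 2 and 3. In liver 5 of 14 heat shock genes were lower in females than in males on HFD at 12 weeks (6 adjusted over the list alone), and Hspa1b had 11.4 ± 7.39 and 94.2 ± 77.2 CPM. The list count was 2 to 6 with 1 library left out. It is not known whether a number names the same animal in both tissues.

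Lipid genes did not all move alike in male liver at 12 weeks. Lpl, the lipoprotein lipase, had a log2 fold change of -1.52 ± 0.22 on HFD, the opposite way to Cidec on the same lipid droplet list. In adipose tissue Ptgds, a prostaglandin synthase, fell by 8.28 ± 1.75 on the log2 scale in HFD males at 12 weeks, in the same libraries as the fall of tract epithelium markers, and Hmox1, which breaks down haem, rose by 2.20 ± 0.24.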
